A study of Caenorhabditis elegans with 24 samples.

How the data were processed

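RNA of whole animals was measured in 24 libraries, 3 for each of 8 groups that were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the TruSeq RNA v2 kit, which does not mark the strand of a transcript, from 1 µg of RNA. The growth protocol, given for the samples of the first table only, describes synchronised animals kept at 20 °C on OP50 bacteria, with those of day 4 transferred daily. Per the submitters' processing notes, reads were aligned with STAR 2.5.4 and counted with featureCounts of the Subread package. The deposited values are raw counts of reads per gene, summed over exons by featureCounts 1.5.2 per the file headers, against the canonical gene set of WormBase release 260. Per the file headers, strand was ignored, and reads that mapped to several places or overlapped several genes were left out, so near-identical paralogs such as the vit and msp genes and genes on opposite strands at one place cannot be separated fully. Each of the 2 deposited tables holds 12 libraries and the same 46778 genes with identical coordinates. Wild type and ceh-60 libraries are all in the first table and libraries with a pqm-1 allele all in the second, so that a difference between the tables cannot be separated from genotype where a comparison crosses them. Gene symbols were found for 43818 of the gene IDs. Where no symbol was found the ID is printed.

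Total counts ranged from 18809461 to 32598349 per library. Within groups, no replicate repeats another: the chi-square per degree of freedom of each pair's counts was 4.04 or more. On simulated counts with 200 changed genes per step, drawn from the real means and library sizes, the test recovered 51% of genes changed by 0.585 on the log2 scale and 71% of those changed by 1 for ceh-60 against wild type on day 1, with 4 false calls among 12891 genes. For the ceh-60 effect in ok485 minus that in wild type it recovered 36% and 57%, with 11 false calls among 13316 genes. For the 2 pqm-1 alleles it was 53% and 68%, with 11 among 13107. Genes here are those tested, so the false share of the calls is larger.

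From the deposited counts, groups were compared with edgeR 4.0.16 in R 4.3.3: genes with too few counts were removed with filterByExpr by group, libraries were scaled with TMM, and quasi-likelihood F-tests were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. There were 3 fits: the 12 libraries of the first table (13137 genes tested, biological coefficient of variation 0.0838, 8 residual degrees of freedom), the 12 of the second (13324 genes, 0.106, 8) and the 18 libraries of day 1 (13589 genes, 0.0972, 12). Of 14 comparisons 13 were planned, and the difference of the ceh-60 effect between the 2 pqm-1 alleles was added after the data had been seen. Groups, comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The rule named ceh-60 and pqm-1, vit-1 to vit-6, the 6 largest rises and falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups' libraries (4 for interactions, allele comparisons and comparisons across tables), and from each described list up to 2 rising and 2 falling members with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

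In total 35 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01, where at least 5 genes had been tested, and again with a correlation estimated from the data. Adjustment was over the lists of a comparison. Members were also adjusted over the list alone. The fixed names of mitochondrially encoded genes matched no symbol, and the protein-coding genes of the mitochondrial chromosome were used for that list instead, a choice made after the tables had been read. The vitellogenin share was the percent of all counts of a library that fell on vit-1 to vit-6, compared by two-sided exact permutation tests. Overlaps of called genes were set beside the number that independent lists would share. Alternatives were DESeq2 1.42.0 with its own size factors, edgeR with RLE size factors, no filter on low counts, a threshold of at least 2-fold, only the compared groups in the fit, the replicate number as a block, and leaving out each library in turn. No scaling moved the median log2 fold change of all genes by more than 0.1.

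The titles give the groups shared replicate numbers, and whether same-numbered libraries deviate together was decided only from the correlation of their deviations from the group means, not from the calls of the blocked fit. For the ceh-60 effect in pqm-1(ok485) it was 0.49, 0.45 and 0.17 for numbers 1 to 3, and for pqm-1(rhd90) against pqm-1(ok485) on day 1 it was 0.47, 0.39 and 0.12. All 6 libraries of the former and 5 of 6 of the latter correlated best with their own number. In these 2 comparisons every correlation exceeded 0.1 and the numbers were taken to pair the libraries, as a finding from the data and not a statement of the labels. In the other comparisons some pair fell at or below 0.1. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15. No library was left out of the main results.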

Results

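RNA from whole Caenorhabditis elegans was sequenced in 24 libraries, 3 in each of 8 groups. Wild type animals of the laboratory strain N2 and ceh-60(ok1485) mutants were taken on adult day 1 and day 4. The strains pqm-1(ok485) and pqm-1(rhd90), and the strains that carry ceh-60(ok1485) together with either pqm-1 allele, were taken on day 1. The combined strains are called the ok485 double mutant and the rhd90 double mutant. ceh-60 encodes a homeodomain protein of the PBX family and pqm-1 a zinc finger transcription factor, both known to act on yolk protein genes in the intestine. Gene counts were deposited in 2 tables, of which the first held the wild type and ceh-60 libraries and the second the libraries with a pqm-1 allele. Between 18809461 and 32598349 counts were assigned to genes per library. The most deeply sequenced library was replicate 2 of wild type day 4 and the least was replicate 2 of the rhd90 double mutant. Levels in CPM (counts scaled to the library's total) are given below as mean ± SD with n = 3 libraries, after TMM scaling within a table unless another scale is named. Each value in parentheses after a gene is its log2 fold change ± SE. Genes were called with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of single genes come from that test. Largest rises and falls are given among ranked genes only, which are genes that passed, had a mean of at least 5 CPM over the compared libraries and did not overlap between the groups. Genes of lower abundance can have larger changes. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples.

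The mutated genes were looked at first, in every group. ceh-60 (WBGene00017690, chromosome X, 6522596 to 6530148, reverse strand) stood at 6.33 ± 0.66 CPM in wild type day 1 and 1.38 ± 0.431 in the ceh-60 mutant. On day 4 its level was 4.78 ± 0.272 CPM in wild type and 0.692 ± 0.12 in the mutant. In the second table it was 8.43 ± 0.831 CPM in pqm-1(ok485), 8.12 ± 0.455 in pqm-1(rhd90), 1.29 ± 0.101 in the ok485 double mutant and 1.55 ± 0.409 in the rhd90 double mutant. ceh-60 transcripts therefore fell in each of the 4 comparisons that carry ok1485, with log2 fold changes of -2.19 ± 0.20 (day 1, adjusted p = 3.52e-06), -2.78 ± 0.21 (day 4, adjusted p = 8.18e-07), -2.71 ± 0.17 (ok485 background, adjusted p = 9.04e-07) and -2.38 ± 0.17 (rhd90 background, adjusted p = 1.76e-06). pqm-1 (WBGene00004096, chromosome II, 11150299 to 11152600, reverse strand) was at 11.2 ± 0.374 CPM in wild type day 1, 26.4 ± 1.9 in wild type day 4, 29.98 ± 0.86 in ceh-60 day 1 and 48.5 ± 2.56 in ceh-60 day 4. Its level was 5.87 ± 0.288 CPM in pqm-1(ok485) and 4.86 ± 0.481 in the ok485 double mutant, against 14.3 ± 1.01 in pqm-1(rhd90) and 23.2 ± 1.65 in the rhd90 double mutant. Coordinates are those of the count tables, whose header names WormBase release 260. The labels do not state which part of either gene an allele removes or alters, so counts over whole genes do not tell whether a transcript is functional.

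**Figure D1:**
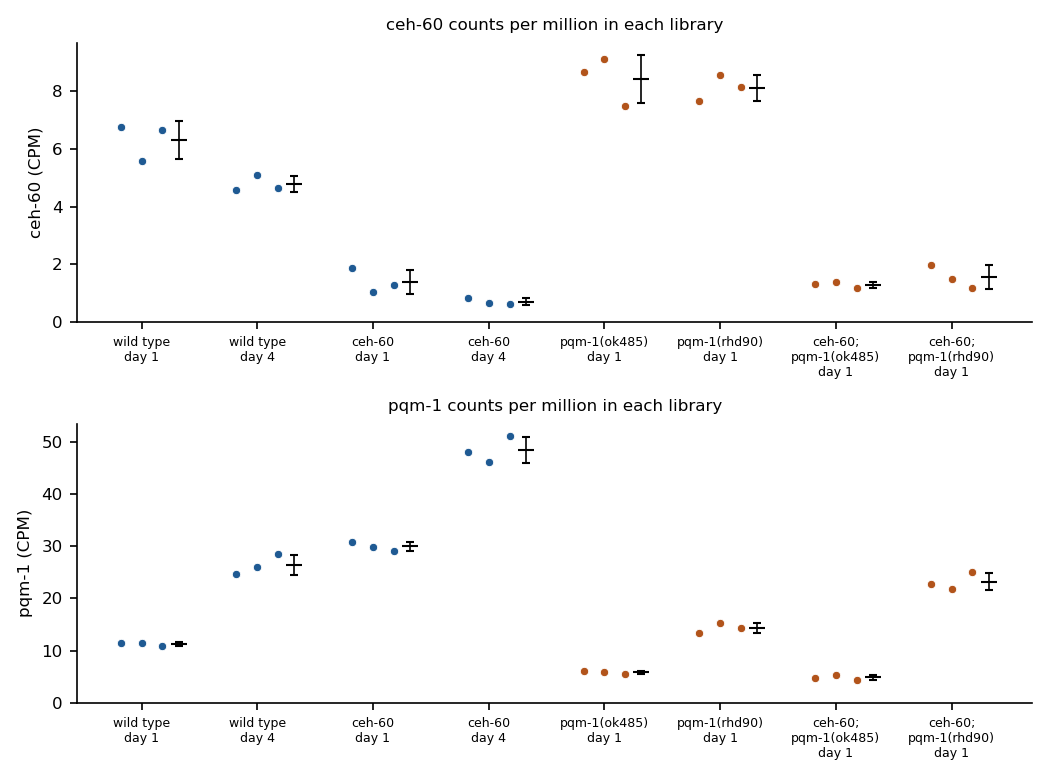
CPM of ceh-60 and pqm-1 in each library (points; blue, first table; orange, second table), with the mean ± SD of 3 libraries per group as a black bar and CPM scaled by TMM within each table. Every library with ceh-60(ok1485) lies below every library without it for ceh-60, and pqm-1 is lowest in both ok485 groups.

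Loss of ceh-60 on day 1 lowered all 6 vitellogenin genes, which encode yolk proteins. vit-5 (WBGene00006929, chromosome X, 3403471 to 3408603) went from 9809 ± 279 CPM in wild type to 30.7 ± 22.6 in the mutant and vit-6 (WBGene00006930, chromosome IV, 8261134 to 8266462) from 29980 ± 2240 to 694 ± 380. vit-2 (WBGene00006926, chromosome X, 5101032 to 5106173) fell from 21720 ± 1440 to 3061 ± 942 CPM. The log2 fold changes were -3.51 ± 0.24 for vit-1, -2.83 ± 0.18 for vit-2, -5.45 ± 0.37 for vit-3, -8.40 ± 0.30 for vit-4, -8.32 ± 0.54 for vit-5 and -5.43 ± 0.43 for vit-6, with adjusted p between 1.97e-09 and 1.04e-06. These 6 genes were also the largest falls among ranked genes. Reads that map to several places were not counted, so the division of signal among the near-identical vit-3, vit-4 and vit-5, and between vit-1 and vit-2, is uncertain. pqm-1 itself was higher in the mutant (1.42 ± 0.07, adjusted p = 2.21e-08). The largest rises among ranked genes were catp-2 (7.0 ± 0.82), Y39G8B.9 (5.87 ± 0.28), nhx-6 (5.69 ± 0.76), pud-3 (4.41 ± 0.39) and C40H1.8 (4.15 ± 0.41), and tbb-6 (4.03 ± 0.41), which encodes a beta-tubulin. catp-2 (WBGene00015338, chromosome V, 4934706 to 4939085) was at 12.33 ± 11.6 CPM in the mutant and 0.0929 ± 0.0511 in wild type. Of 13137 genes tested, 3354 passed, 2111 higher and 1243 lower in the mutant, and 978 of them changed by at least 2-fold (790 higher, 188 lower). The number passing was 1899 without replicate 1 of ceh-60 day 1, 2090 without replicate 2 of wild type day 1 and 2100 without replicate 3 of wild type day 1.

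Among intestine genes in the day 1 mutant 24 rose, 2 fell and 3 did not pass of 29 tested (25 rose and 2 fell adjusted over the list alone, camera adjusted p = 9.19e-12 for higher, adjusted p = 0.0661 with an estimated correlation). The cathepsin B protease genes cpr-1 (3.04 ± 0.09) and cpr-4 (2.67 ± 0.11) were among those that rose, while cpl-1 (-0.44 ± 0.10) and cpr-6 (-0.23 ± 0.05) were lower. Of the immune targets of the p38 kinase PMK-1, 8 rose and 6 did not pass of 14 tested (11 rose adjusted over the list alone, camera adjusted p = 4.54e-06 for higher, adjusted p = 0.0794 with an estimated correlation). clec-67 (2.87 ± 0.20) and lys-2 (1.96 ± 0.08) were among them. Of lysozyme and antimicrobial peptide genes, 25 rose and 35 did not pass of 60 tested (26 rose adjusted over the list alone, camera adjusted p = 5.34e-09 for higher, adjusted p = 0.0661 with an estimated correlation), with lys-1 (1.64 ± 0.06) as a further example. Of C-type lectin genes, which encode sugar-binding proteins, 44 rose, 6 fell and 49 did not pass of 99 tested (50 rose and 7 fell adjusted over the list alone, camera adjusted p = 3.52e-07 for higher, adjusted p = 0.0661 with an estimated correlation). clec-63 (1.85 ± 0.09) rose and clec-83 (-0.60 ± 0.08) fell. In the intracellular pathogen response, 14 rose and 11 did not pass of 25 tested (16 rose adjusted over the list alone, camera adjusted p = 1.64e-07 for higher, adjusted p = 0.0661 with an estimated correlation), among them pals-24 (1.51 ± 0.10) and skr-3 (1.4 ± 0.09). For glutathione and SKN-1 genes 17 rose and 17 did not pass of 34 tested (18 rose adjusted over the list alone, camera adjusted p = 4.36e-09 for higher, adjusted p = 0.0661 with an estimated correlation). gst-10 (2.81 ± 0.17) and gst-28 (2.17 ± 0.14) were examples. For UDP-glucuronosyltransferases 29 rose, 1 fell and 24 did not pass of 54 tested (34 rose and 2 fell adjusted over the list alone, camera adjusted p = 2.26e-08 for higher, adjusted p = 0.102 with an estimated correlation), with ugt-19 (2.21 ± 0.14) and ugt-46 (1.2 ± 0.09) higher and ugt-47 (-0.84 ± 0.12) lower. The list tests used camera with a preset correlation between genes of 0.01, and none of its calls in any comparison held at the threshold when the correlation was estimated from the data.

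Further lists were counted in the day 1 mutant. Of genes for lipolysis and fat oxidation, 20 rose, 1 fell and 14 did not pass of 35 tested (21 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.000176 for higher, adjusted p = 0.145 with an estimated correlation). The lipase gene lipl-5 (1.29 ± 0.07) and the peroxisomal gene dhs-28 (0.66 ± 0.07) rose, and the acyl-CoA synthetase gene acs-2 (-1.1 ± 0.16) fell. Among autophagy and lysosome genes 22 rose, 2 fell and 15 did not pass of 39 tested (23 rose and 3 fell adjusted over the list alone, camera adjusted p = 6.86e-05 for higher, adjusted p = 0.0932 with an estimated correlation). sqst-1 (0.95 ± 0.11) and lmp-1 (0.57 ± 0.05) were higher. Of body wall muscle genes, 15 rose and 7 did not pass of 22 tested (17 rose adjusted over the list alone, camera adjusted p = 4.05e-05 for higher, adjusted p = 0.469 with an estimated correlation). unc-54 (0.76 ± 0.14) and atn-1 (0.51 ± 0.07) were among them. Of ribosomal protein genes, 2 rose, 27 fell and 50 did not pass of 79 tested (2 rose and 36 fell adjusted over the list alone, camera adjusted p = 8.62e-09 for lower, adjusted p = 0.474 with an estimated correlation). rps-4 (-0.21 ± 0.05) and rpl-11.1 (-0.21 ± 0.05) were among the lower genes. In the germline list 12 fell and 27 did not pass of 39 tested (13 fell adjusted over the list alone, camera adjusted p = 7.41e-05 for lower, adjusted p = 0.485 with an estimated correlation), and syp-3 (-0.30 ± 0.07), which acts in chromosome pairing at meiosis, was among the lower genes. For genes of the early zygotic embryo 1 rose, 12 fell and 34 did not pass of 47 tested (1 rose and 12 fell adjusted over the list alone, camera adjusted p = 6.06e-06 for lower, adjusted p = 0.378 with an estimated correlation), with sdz-30 (-1.1 ± 0.20) lower and sdz-35 (2.78 ± 0.39) higher.

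Vitellogenin genes were low again in ceh-60 mutants on day 4. vit-5 was at 47.1 ± 26.6 CPM against 8421 ± 762 in wild type, and the log2 fold changes ran from -1.85 ± 0.18 for vit-2 to -7.63 ± 0.30 for vit-4. Between them lay vit-1 (-2.67 ± 0.23), vit-3 (-3.44 ± 0.34) and vit-6 (-5.32 ± 0.42) and vit-5 itself at -7.49 ± 0.52. T05E12.3 (-3.16 ± 0.23) fell as well. Among ranked genes the insulin-like peptide gene ins-35 (6.58 ± 0.45) and the lectin gene clec-174 (6.19 ± 0.29) rose most, followed by pud-3 (5.79 ± 0.28), Y68A4A.13 (5.53 ± 0.30), clec-42 (4.77 ± 0.52) and dod-22 (4.69 ± 0.27). pqm-1 was again higher (0.88 ± 0.06, adjusted p = 4.69e-07). In total 3201 of 13137 genes passed, 2118 higher and 1083 lower, with 897 at 2-fold or more. DESeq2 with its own size factors divided the calls differently, with 1864 higher and 1543 lower.

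Most of the intestine list rose on day 4, where 26 rose and 3 did not pass of 29 tested (26 rose adjusted over the list alone, camera adjusted p = 2.74e-18 for higher, adjusted p = 0.0713 with an estimated correlation). The protease genes cpr-1 (2.32 ± 0.08) and asp-1 (1.92 ± 0.09) were examples. Of PMK-1 targets, 10 rose and 4 did not pass of 14 tested (10 rose adjusted over the list alone, camera adjusted p = 3.19e-08 for higher, adjusted p = 0.0713 with an estimated correlation). clec-67 (4.57 ± 0.21) and K08D8.5 (2.01 ± 0.10) were among them. Of lysozyme and antimicrobial peptide genes, 29 rose and 31 did not pass of 60 tested (32 rose and 2 fell adjusted over the list alone, camera adjusted p = 4.69e-08 for higher, adjusted p = 0.105 with an estimated correlation). lys-1 (1.18 ± 0.06) and lys-8 (1.59 ± 0.09) were higher. In lipolysis and fat oxidation 19 rose, 1 fell and 15 did not pass of 35 tested (19 rose and 2 fell adjusted over the list alone, camera adjusted p = 6.45e-06 for higher, adjusted p = 0.122 with an estimated correlation), and the lipase gene lipl-1 (3.87 ± 0.22) was an example beside lipl-5 (1.17 ± 0.07). For fat synthesis and desaturation 13 rose and 15 did not pass of 28 tested (13 rose adjusted over the list alone, camera adjusted p = 0.00981 for higher, adjusted p = 0.415 with an estimated correlation), such as the elongase elo-6 (1.2 ± 0.12) and the desaturase fat-2 (0.43 ± 0.05). For lipid binding and transport 12 rose, 1 fell and 6 did not pass of 19 tested (12 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.000883 for higher, adjusted p = 0.225 with an estimated correlation). lbp-8 (1.51 ± 0.24) and dsc-4 (1.24 ± 0.09) were higher. In the oocyte and eggshell list 9 fell and 13 did not pass of 22 tested (11 fell adjusted over the list alone, camera adjusted p = 0.000204 for lower, adjusted p = 0.578 with an estimated correlation). egg-4 (-0.26 ± 0.06) and egg-2 (-0.24 ± 0.06) were among them. In the cell division list 9 fell and 23 did not pass of 32 tested (12 fell adjusted over the list alone, camera adjusted p = 7.80e-05 for lower, adjusted p = 0.658 with an estimated correlation). cdc-6 (-0.18 ± 0.04) and cyb-2.1 (-0.24 ± 0.05) were among them.

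The test of whether the effect of ceh-60 loss differed between the ages asked for genes whose mutant-to-wild-type ratio on day 4 departed from that on day 1. The sodium-proton exchanger gene nhx-6 (-6.20 ± 1.16), tbb-6 (-3.84 ± 0.56) and dod-3 (-3.70 ± 0.58) and the lectin gene clec-47 (-3.70 ± 0.35) were raised less, or lowered more, on day 4. The acyl-CoA synthetase gene acs-2 (2.86 ± 0.21) and F40F8.5 (2.14 ± 0.16) went the other way. clec-174 (5.15 ± 1.13), vit-3 (2.01 ± 0.45), vit-2 (0.98 ± 0.24) and cyp-35A5 (2.17 ± 0.53) passed too, also with a higher effect on day 4, but these calls depended on single libraries. The call of clec-174 was lost on leaving out 2 of 12 libraries, wild type day 1 replicates 2 and 3. Adjusted p was 0.097 to 0.214 without them. That of vit-3 was lost on leaving out 7 of 12 libraries, wild type day 1 replicates 1 and 3, wild type day 4 replicates 1 and 3, ceh-60 day 1 replicate 3 and ceh-60 day 4 replicates 1 and 2. Adjusted p was 0.0513 to 0.0796 without them. For vit-2 it was 9 of 12 libraries, wild type day 1 replicates 1, 2 and 3, wild type day 4 replicates 1, 2 and 3, ceh-60 day 1 replicate 3 and ceh-60 day 4 replicates 1 and 2. Adjusted p was 0.0665 to 0.119 without them. For cyp-35A5 it was 10 of 12 libraries, wild type day 1 replicates 1, 2 and 3, wild type day 4 replicates 1, 2 and 3, ceh-60 day 1 replicate 1 and ceh-60 day 4 replicates 1, 2 and 3. Adjusted p was 0.0569 to 0.11 without them. pqm-1 was raised less on day 4 (-0.54 ± 0.09, adjusted p = 0.00537). ceh-60 itself gave no difference that passed (-0.59 ± 0.29, adjusted p = 0.321). Of the ribosomal protein genes, 10 had a higher effect on day 4 and 69 did not pass of 79 tested (37 had a higher effect on day 4 adjusted over the list alone, camera adjusted p = 1.01e-16 for higher, adjusted p = 0.562 with an estimated correlation). In the DAF-16 stress target list 5 had a lower effect and 12 did not pass of 17 tested (1 had a higher effect and 5 had a lower effect adjusted over the list alone, camera adjusted p = 2.38e-05 for lower, adjusted p = 0.562 with an estimated correlation), among them dod-3 and cdr-2 (-1.74 ± 0.19). In the intracellular pathogen response 4 had a lower effect and 21 did not pass of 25 tested (1 had a higher effect and 6 had a lower effect adjusted over the list alone, camera adjusted p = 0.0135 for lower, adjusted p = 0.562 with an estimated correlation). pals-24 (-1.25 ± 0.14) and skr-5 (-3.32 ± 0.61) were among them. Altogether 531 genes passed, 239 with a higher and 292 with a lower effect on day 4, and 905 passed without a filter on low counts. The number was 306 without wild type day 1 replicate 3, 343 without wild type day 4 replicate 1, 338 without wild type day 4 replicate 2 and 324 without ceh-60 day 4 replicate 2.

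Between day 1 and day 4 of adulthood, the metallothionein gene mtl-1 (7.40 ± 0.51) rose most among ranked genes in wild type animals, from 0.165 ± 0.169 to 29.2 ± 12 CPM, followed by F15B9.6 (6.19 ± 0.42), asp-17 (5.62 ± 0.28), C50F7.5 (5.24 ± 0.40) and F08G2.5 (4.71 ± 0.22) and the heat shock gene hsp-70 (4.67 ± 0.66). The largest falls among ranked genes were col-93 (-6.03 ± 0.40), sri-40 (-5.49 ± 0.15), acdh-2 (-4.91 ± 0.26), col-20 (-4.88 ± 0.31), col-124 (-4.19 ± 0.51) and F53F1.4 (-4.12 ± 0.45). pqm-1 rose with age (1.23 ± 0.07, adjusted p = 1.75e-08), while ceh-60 did not change at the threshold (-0.40 ± 0.17, adjusted p = 0.0623, or 0.0187 when only these groups were fitted). Among vitellogenins vit-1 (-2.59 ± 0.23), vit-3 (-1.76 ± 0.31) and vit-4 (-0.97 ± 0.20) fell. All 79 ribosomal protein genes tested fell (all 79 adjusted over the list alone, camera adjusted p = 1.23e-39 for lower, adjusted p = 0.520 with an estimated correlation), with rps-13 (-1.03 ± 0.04) and rpl-29 (-0.89 ± 0.04) as examples. In the body wall muscle list 21 fell and 1 did not pass of 22 tested (21 fell adjusted over the list alone, camera adjusted p = 1.85e-09 for lower, adjusted p = 0.660 with an estimated correlation). tnt-2 (-2.39 ± 0.12) and pat-10 (-1.92 ± 0.10) were among them. Of the collagens, 4 rose, 40 fell and 39 did not pass of 83 tested (4 rose and 40 fell adjusted over the list alone, camera adjusted p = 6.99e-06 for lower, adjusted p = 0.720 with an estimated correlation). Genes of oxidative phosphorylation encoded in the nucleus behaved as follows: 1 rose, 29 fell and 1 did not pass of 31 tested (1 rose and 29 fell adjusted over the list alone, camera adjusted p = 2.13e-10 for lower, adjusted p = 0.660 with an estimated correlation). nuo-6 (-0.52 ± 0.04) and nuo-1 (-0.46 ± 0.04) were among them. In the cell division list 14 rose and 18 did not pass of 32 tested (14 rose adjusted over the list alone, camera adjusted p = 0.0176 for higher, adjusted p = 0.798 with an estimated correlation). cyb-1 (0.53 ± 0.05) and pcn-1 (0.38 ± 0.05) were among them. Of 13137 genes, 7193 passed, 3735 higher and 3458 lower on day 4, with 1778 at 2-fold or more.

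Among ranked genes in ceh-60 mutants, the same span of age raised clec-174 (6.94 ± 0.32), mtl-1 (6.26 ± 0.45) and lipl-1 (5.01 ± 0.25), the alcohol dehydrogenase gene adh-1 (4.67 ± 0.34), asp-17 (4.37 ± 0.18) and drd-50 (4.36 ± 0.21) most. The 6 largest falls among ranked genes were all of collagen genes, col-93 (-7.29 ± 0.43), col-129 (-6.63 ± 0.99), col-139 (-6.50 ± 1.05), col-94 (-6.12 ± 0.48), col-20 (-5.68 ± 0.32) and col-124 (-5.58 ± 0.54). Here pqm-1 rose (0.69 ± 0.06, adjusted p = 1.36e-06), ceh-60 transcripts fell (-0.99 ± 0.24, adjusted p = 0.00348), and vit-1 (-1.75 ± 0.23) fell among the vitellogenins. The 79 ribosomal protein genes all fell again (all 79 adjusted over the list alone, camera adjusted p = 2.20e-40 for lower, adjusted p = 0.290 with an estimated correlation), for example rps-7 (-0.91 ± 0.05) and rps-18 (-0.79 ± 0.04). In the body wall muscle list 21 fell and 1 did not pass of 22 tested (22 fell adjusted over the list alone, camera adjusted p = 1.36e-12 for lower, adjusted p = 0.432 with an estimated correlation). tnt-2 (-2.58 ± 0.12) and mlc-2 (-1.99 ± 0.10) were among them. For collagens 15 rose, 46 fell and 22 did not pass of 83 tested (17 rose and 47 fell adjusted over the list alone, camera adjusted p = 5.79e-06 for lower, adjusted p = 0.645 with an estimated correlation). In the insulin list 12 rose and 8 did not pass of 20 tested (12 rose adjusted over the list alone, camera adjusted p = 0.00354 for higher, adjusted p = 0.226 with an estimated correlation). ins-22 (2.97 ± 0.30) and pdk-1 (1.15 ± 0.10) were among them. Major sperm protein genes, expressed at low levels in all first-table libraries, behaved as follows: 19 fell of 19 tested (19 fell adjusted over the list alone, camera adjusted p = 0.000136 for lower, adjusted p = 0.662 with an estimated correlation). A total of 6909 of 13137 genes passed, 3718 higher and 3191 lower, with 1790 at 2-fold or more.

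The effect of ceh-60 loss was then measured within each pqm-1 mutant. In the ok485 background all 6 vitellogenins fell, and vit-5 went from 11270 ± 1930 to 6.43 ± 1.71 CPM and vit-2 from 30570 ± 4280 to 1055 ± 466. The log2 fold changes were vit-1 (-3.92 ± 0.37), vit-2 (-4.86 ± 0.30), vit-3 (-7.21 ± 0.50), vit-4 (-9.89 ± 0.18), vit-5 (-10.77 ± 0.47) and vit-6 (-8.03 ± 0.61). pqm-1 was not raised here (-0.28 ± 0.10, adjusted p = 0.129). Among ranked genes the claudin-like gene cld-1 (6.46 ± 0.76) and dod-21 (5.71 ± 0.66), Y39G8B.9 (4.22 ± 0.21) and F33H12.7 (2.77 ± 0.22) rose most, followed by the glutathione transferase gene gst-38 (2.66 ± 0.18) and B0205.13 (2.4 ± 0.31). Of PMK-1 targets, 10 rose and 4 did not pass of 14 tested (10 rose adjusted over the list alone, camera adjusted p = 2.04e-08 for higher, adjusted p = 0.0750 with an estimated correlation). clec-67 (2.39 ± 0.21) and lys-2 (2.13 ± 0.11) were examples. For endoplasmic reticulum chaperones 7 rose and 6 did not pass of 13 tested (9 rose adjusted over the list alone, camera adjusted p = 4.61e-08 for higher, adjusted p = 0.140 with an estimated correlation), such as calreticulin, crt-1 (0.71 ± 0.06), and pdi-3 (0.52 ± 0.05). For glutathione and SKN-1 genes 13 rose and 19 did not pass of 32 tested (14 rose adjusted over the list alone, camera adjusted p = 4.91e-10 for higher, adjusted p = 0.0977 with an estimated correlation), gst-6 (1.47 ± 0.09) among them. In the intestine list 19 rose, 2 fell and 8 did not pass of 29 tested (21 rose and 4 fell adjusted over the list alone, camera adjusted p = 1.74e-10 for higher, adjusted p = 0.190 with an estimated correlation), with cpr-5 (2.04 ± 0.10) and pho-1 (0.89 ± 0.07) higher and cpl-1 (-1.35 ± 0.15) lower. Of 13324 genes, 1195 passed, 634 higher and 561 lower, with 420 at 2-fold or more. Same-numbered libraries deviated together in this pair of groups, and with the replicate number as a block 2160 genes passed, 1081 higher and 1079 lower. Without replicate 3 of the ok485 double mutant 738 passed.

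In the rhd90 background ceh-60 loss lowered vit-1 (-3.57 ± 0.36), vit-2 (-6.20 ± 0.32), vit-3 (-5.51 ± 0.45), vit-4 (-8.97 ± 0.16), vit-5 (-7.20 ± 0.40) and vit-6 (-5.38 ± 0.54), and vit-5 went from 14290 ± 395 to 97.2 ± 52.1 CPM. pqm-1 transcripts rose (0.69 ± 0.09, adjusted p = 0.000205). The largest rises among ranked genes were Y39G8B.9 (5.62 ± 0.25), ins-35 (5.06 ± 0.30), pud-3 (4.23 ± 0.72), F15B9.6 (3.88 ± 0.29), cdr-4 (3.83 ± 0.23) and tbb-6 (3.77 ± 0.30). Of PMK-1 targets, 9 rose and 5 did not pass of 14 tested (11 rose adjusted over the list alone, camera adjusted p = 5.36e-08 for higher, adjusted p = 0.0670 with an estimated correlation). clec-67 (2.78 ± 0.23) and lys-2 (2.19 ± 0.11) were among them. In the intracellular pathogen response 15 rose and 9 did not pass of 24 tested (17 rose and 2 fell adjusted over the list alone, camera adjusted p = 5.70e-08 for higher, adjusted p = 0.0670 with an estimated correlation), including the Skp1-related genes skr-5 (3.57 ± 0.39) and skr-3 (1.59 ± 0.15). Among glutathione and SKN-1 genes 17 rose and 15 did not pass of 32 tested (18 rose adjusted over the list alone, camera adjusted p = 8.16e-09 for higher, adjusted p = 0.0920 with an estimated correlation), gst-6 (2.12 ± 0.09) among them. For endoplasmic reticulum chaperones 8 rose and 5 did not pass of 13 tested (8 rose adjusted over the list alone, camera adjusted p = 9.53e-07 for higher, adjusted p = 0.147 with an estimated correlation). crt-1 (0.65 ± 0.06) and enpl-1 (0.42 ± 0.04) were examples. In the intestine list 21 rose, 1 fell and 7 did not pass of 29 tested (21 rose and 1 fell adjusted over the list alone, camera adjusted p = 8.30e-11 for higher, adjusted p = 0.159 with an estimated correlation). cpr-5 (1.79 ± 0.10) and pho-1 (1.07 ± 0.07) were among them. In total 1581 of 13324 genes passed, 1305 higher and 276 lower, with 580 at 2-fold or more.

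The genes called for ceh-60 loss were compared between pairs of comparisons that share no library. Day 1 and day 4 shared 1357 genes called higher and 309 called lower, where independent lists of these sizes would share 340 and 102. Another 35 were called in opposite directions. Wild type day 1 and the ok485 background shared 548 higher and 164 lower genes (103 and 53.8 for independent lists, 34 opposite). With the rhd90 background day 1 shared 1092 and 145 (212 and 26.5, 4 opposite). Both pqm-1 backgrounds shared 565 and 167 (62.1 and 11.6, 5 opposite). Pearson's r of the log2 fold changes across genes, which are not independent replicates, was 0.502 for day 1 with day 4, 0.6 with the ok485 background, 0.808 with the rhd90 background, and 0.621 between both backgrounds.

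**Figure D2:**
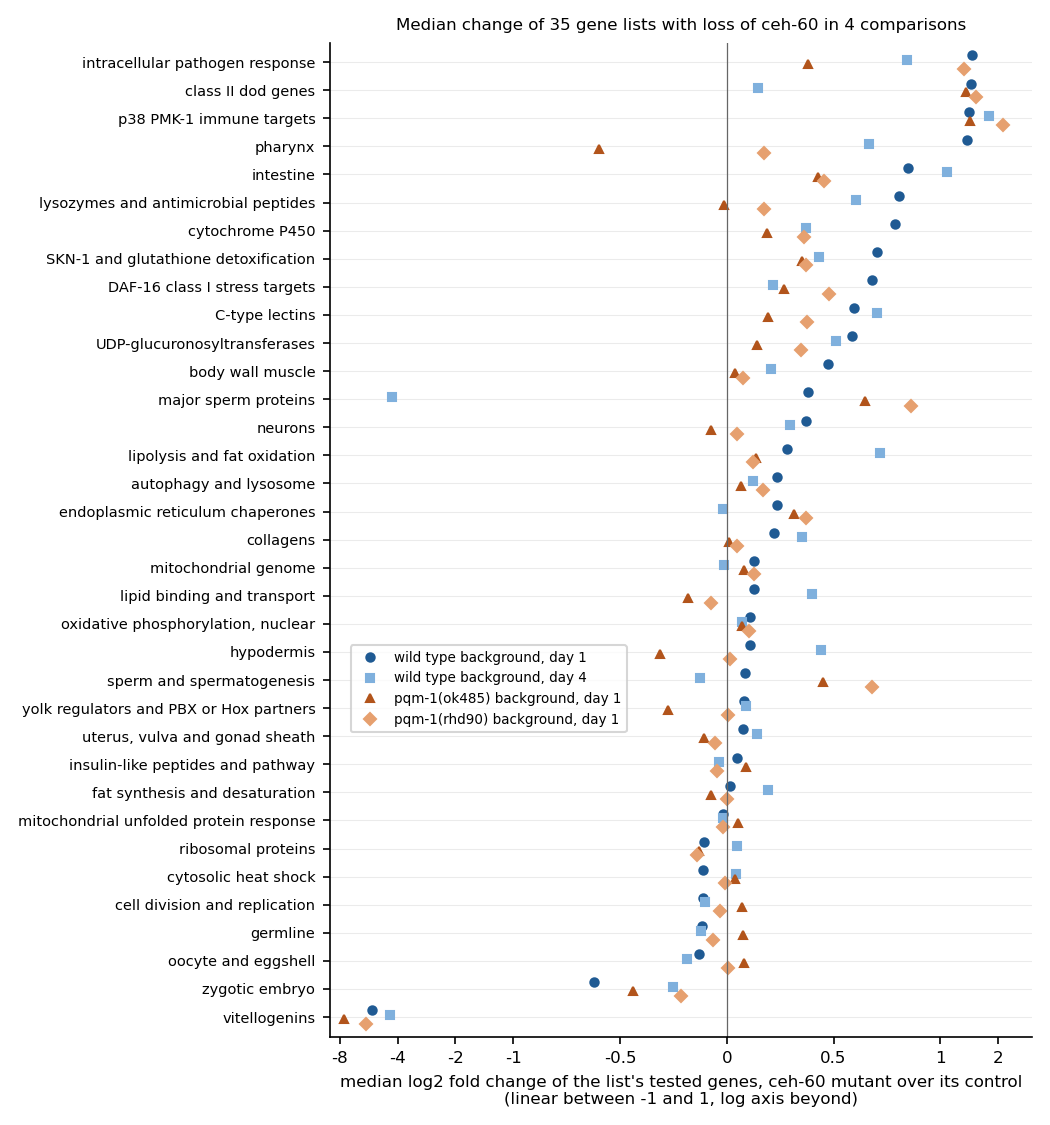
Median log2 fold change of each of the 35 gene lists (vertical axis) for ceh-60 loss in wild type day 1 (circles), wild type day 4 (squares), pqm-1(ok485) (triangles) and pqm-1(rhd90) (diamonds), on a horizontal axis that is linear between -1 and 1 and logarithmic beyond. Vitellogenins lie far to the left in all 4 comparisons, at -5.44, -4.38, -7.62 and -5.86, and PMK-1 targets to the right at 1.42, 1.80, 1.43 and 2.11.

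The ceh-60 effect was compared between backgrounds by interactions over the 18 day 1 libraries. Background and table coincide, so only a shift shared by a table cancels, not a ceh-60 effect that differs between tables. Against the wild type background, the effect in pqm-1(ok485) was more negative for Y50D7A.10 (-5.09 ± 0.28), F55G11.4 (-2.69 ± 0.44) and myo-2 (-2.64 ± 0.42), the last encoding a pharyngeal myosin, and vit-2 (-2.0 ± 0.36). pqm-1 itself gave -1.67 ± 0.12 (adjusted p = 5.47e-07). The effect was more positive for dod-21 (4.27 ± 1.05), asp-12 (2.13 ± 0.50), ZC317.7 (0.76 ± 0.17) and Y46H3C.7 (0.66 ± 0.14), and also more negative for vit-4 (-1.46 ± 0.37), vit-5 (-2.43 ± 0.60) and vit-6 (-2.57 ± 0.66). ZC317.7 and Y46H3C.7 kept their calls with each of the 12 libraries left out in turn. The call of dod-21 was lost on leaving out 8 of 12 libraries, wild type replicates 1 and 2, ceh-60 replicate 3, pqm-1(ok485) replicates 1, 2 and 3 and ok485 double mutant replicates 1 and 3. Adjusted p was 0.0517 to 0.0602 without them. That of asp-12 was lost on leaving out 6 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicate 1, pqm-1(ok485) replicates 2 and 3 and ok485 double mutant replicate 1. Adjusted p was 0.0507 to 0.0773 without them. For vit-4 it was 6 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicates 2 and 3 and ok485 double mutant replicates 2 and 3. Adjusted p was 0.0562 to 0.108 without them, and 0.0832 with only the compared groups fitted. For vit-5 it was 6 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicate 2, pqm-1(ok485) replicate 1 and ok485 double mutant replicates 2 and 3. Adjusted p was 0.0504 to 0.0887 without them. For vit-6 it was 7 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicates 2 and 3, pqm-1(ok485) replicate 1 and ok485 double mutant replicates 2 and 3. Adjusted p was 0.052 to 0.0887 without them. In the lysozyme and antimicrobial peptide list 12 had a lower effect and 41 did not pass of 53 tested (26 had a lower effect adjusted over the list alone, camera adjusted p = 3.25e-09 for lower, adjusted p = 0.345 with an estimated correlation). spp-1 (-1.07 ± 0.15) and nlp-27 (-0.94 ± 0.15) were among them. For C-type lectins 1 had a higher effect, 14 had a lower effect and 100 did not pass of 115 tested (2 had a higher effect and 17 had a lower effect adjusted over the list alone, camera adjusted p = 0.0346 for lower, adjusted p = 0.449 with an estimated correlation), with clec-7 (-2.07 ± 0.39) and clec-10 (-1.4 ± 0.22) lower and a median of -0.30 beside a mean of 0.23. In the intracellular pathogen response 5 had a lower effect and 20 did not pass of 25 tested (8 had a lower effect adjusted over the list alone, camera adjusted p = 5.41e-05 for lower, adjusted p = 0.227 with an estimated correlation), skr-5 (-4.18 ± 0.79) among them. Of 13589 genes, 602 passed, 36 higher and 566 lower. DESeq2 called 920 (183 higher, 737 lower), and 388 passed when only the compared groups were fitted. The number was 220 without ceh-60 replicate 1, 1044, 296 and 337 without wild type replicates 1, 2 and 3, and 354 and 235 without replicates 1 and 3 of the ok485 double mutant.

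Against the wild type background, the ceh-60 effect in pqm-1(rhd90) was more negative for vit-2 (-3.39 ± 0.36), cls-3 (-1.98 ± 0.12), which encodes a protein of the microtubule-binding CLASP family, and pqm-1 (-0.74 ± 0.11). It was more positive for WBGene00014954 (1.85 ± 0.27), WBGene00014955 (1.79 ± 0.28) and F36D3.1 (0.68 ± 0.09). C15A11.7 (-1.61 ± 0.32), nspg-11 (-1.3 ± 0.24) and usp-50 (0.62 ± 0.12) passed as well. The call of C15A11.7 was lost on leaving out 9 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicate 3, pqm-1(rhd90) replicates 1, 2 and 3 and rhd90 double mutant replicates 1, 2 and 3. Adjusted p was 0.06 to 0.143 without them, and 0.116 with only the compared groups fitted. That of nspg-11 was lost on leaving out 8 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicates 1 and 3, pqm-1(rhd90) replicates 1 and 3 and rhd90 double mutant replicates 2 and 3. Adjusted p was 0.0521 to 0.0993 without them. For usp-50 it was 7 of 12 libraries, ceh-60 replicates 1 and 3, pqm-1(rhd90) replicates 1 and 3 and rhd90 double mutant replicates 1, 2 and 3. Adjusted p was 0.0628 to 0.0993 without them. Only 37 genes passed, 11 higher and 26 lower, 1172 had an unadjusted p under 0.05, and DESeq2 called 101 (17 higher, 84 lower). Without a filter on low counts 151 passed. The number was 68, 17 and 16 without wild type replicates 1 to 3, 24, 69 and 22 without ceh-60 replicates 1 to 3, 16 and 16 without pqm-1(rhd90) replicates 2 and 3, and 18, 14 and 21 without rhd90 double mutant replicates 1 to 3.

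The 2 backgrounds were also compared with each other, within the second table, in a comparison chosen after the data had been seen. Relative to ok485, the effect in rhd90 was more positive for Y50D7A.10 (5.14 ± 0.34), vit-5 (3.58 ± 0.48) and hid-1 (2.06 ± 0.14) and for pqm-1 (0.97 ± 0.14), and more negative for cls-3 (-2.15 ± 0.14). WBGene00020981 (1.98 ± 0.29), W02D7.6 (-0.54 ± 0.09) and fbxa-192 (-1.05 ± 0.17) passed as well. The call of WBGene00020981 was lost on leaving out 4 of 12 libraries, pqm-1(rhd90) replicates 1 and 2 and ok485 double mutant replicates 2 and 3. Adjusted p was 0.0505 to 0.0612 without them. That of W02D7.6 was lost on leaving out 8 of 12 libraries, pqm-1(ok485) replicate 2, pqm-1(rhd90) replicates 2 and 3, ok485 double mutant replicates 1, 2 and 3 and rhd90 double mutant replicates 1 and 3. Adjusted p was 0.0594 to 0.107 without them. For fbxa-192 it was 9 of 12 libraries, pqm-1(ok485) replicates 2 and 3, pqm-1(rhd90) replicates 2 and 3, ok485 double mutant replicates 1, 2 and 3 and rhd90 double mutant replicates 1 and 3. Adjusted p was 0.0542 to 0.1 without them. Here 46 genes passed, 42 higher and 4 lower, of 13324 tested, 1263 had an unadjusted p under 0.05, and DESeq2 called 106 higher and 13 lower. The number ran from 14 without ok485 double mutant replicate 2 to 100 without rhd90 double mutant replicate 2. It was 18 and 17 without pqm-1(ok485) replicates 2 and 3, 18, 15 and 16 without pqm-1(rhd90) replicates 1 to 3, 19 and 19 without ok485 double mutant replicates 1 and 3, and 21 and 16 without rhd90 double mutant replicates 1 and 3.

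Between the pqm-1 alleles, most sperm genes differed. In ceh-60(+) animals, major sperm protein genes behaved as follows: 24 were lower in rhd90 and 1 did not pass of 25 tested (25 were lower in rhd90 adjusted over the list alone, camera adjusted p = 1.62e-20 for lower, adjusted p = 0.471 with an estimated correlation). msp-57 (-3.71 ± 0.58) and msp-142 (-3.69 ± 0.60) were among them. For sperm and spermatogenesis genes 30 were lower and 11 did not pass of 41 tested (32 were lower adjusted over the list alone, camera adjusted p = 2.62e-17 for lower, adjusted p = 0.471 with an estimated correlation). nspd-1 (-3.50 ± 0.55) and ssp-35 (-3.69 ± 0.60) were among them. Reads shared among the near-identical msp genes were not counted, so the values of single members are uncertain. The collagen gene col-135 (-6.19 ± 0.29) was nearly silent in rhd90, and gipc-1 (-3.58 ± 0.67), nsph-3.2 (-3.56 ± 0.62) and gipc-2 (-3.39 ± 0.60) were the next lowest of the ranked genes, but the last 3 calls were lost without pqm-1(rhd90) replicate 3 (adjusted p = 0.0635 for gipc-1, 0.0525 for nsph-3.2 and 0.053 for gipc-2). Higher in rhd90 were C08F11.7 (4.54 ± 0.21), F35F10.5 (2.90 ± 0.30) and asp-12 (2.85 ± 0.39). pqm-1 transcripts were higher in rhd90 (1.29 ± 0.10, adjusted p = 2.10e-05), and ceh-60 did not differ at the threshold (-0.06 ± 0.15, adjusted p = 0.87). For collagens 1 were higher, 34 were lower and 76 did not pass of 111 tested (4 were higher and 63 were lower adjusted over the list alone, camera adjusted p = 7.26e-15 for lower, adjusted p = 0.471 with an estimated correlation), col-160 (-0.90 ± 0.15) among them. In all 984 of 13324 genes passed, 222 higher and 762 lower in rhd90. Same-numbered libraries deviated together, and with the replicate number as a block 2069 passed (732 higher, 1337 lower). That block brought the lipolysis list (adjusted p = 0.0394) and the nuclear oxidative phosphorylation list (0.0449) past the threshold of camera and took the cell division list below it (0.0548). The number passing was 2186, 425 and 616 without pqm-1(ok485) replicates 1, 2 and 3, 349 and 187 without pqm-1(rhd90) replicates 1 and 3, and 616 with only the compared groups.

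The alleles were also compared in ceh-60 mutants. vit-5 (3.92 ± 0.38), vit-6 (2.66 ± 0.48), vit-4 (1.27 ± 0.20) and vit-3 (1.76 ± 0.42) were higher in the rhd90 double mutant and vit-2 (-1.28 ± 0.26) was lower, all at levels far below those of animals with ceh-60. The call of vit-3 was lost without replicate 2 of the ok485 double mutant (adjusted p = 0.0545) and without replicates 1 and 3 of the rhd90 double mutant (0.0664 and 0.0645). When the allele difference in ceh-60 mutants was tested against that in ceh-60(+) animals, vit-5 passed (adjusted p = 0.0113), while vit-2 (adjusted p = 0.19), vit-3 (adjusted p = 0.312), vit-4 (adjusted p = 0.141) and vit-6 (adjusted p = 0.138) did not. The largest differences among ranked genes were, upward, Y50D7A.10 (6.03 ± 0.27) and C08F11.7 (4.40 ± 0.22), vit-5 and pud-4 (3.92 ± 0.74), and downward col-135 (-5.44 ± 0.25), col-133 (-3.93 ± 0.70), Y57G11A.2 (-3.69 ± 0.48) and T10E9.4 (-3.54 ± 0.49). Major sperm protein genes behaved as follows: 25 were lower in rhd90 of 25 tested (25 were lower in rhd90 adjusted over the list alone, camera adjusted p = 4.86e-20 for lower, adjusted p = 0.471 with an estimated correlation). msp-57 (-3.06 ± 0.48) and msp-142 (-4.0 ± 0.55) were among them. For sperm and spermatogenesis genes 31 were lower and 10 did not pass of 41 tested (31 were lower adjusted over the list alone, camera adjusted p = 5.68e-17 for lower, adjusted p = 0.471 with an estimated correlation). ssp-10 (-3.50 ± 0.49) and nspd-1 (-3.03 ± 0.48) were among them. For collagens 4 were higher, 46 were lower and 61 did not pass of 111 tested (5 were higher and 65 were lower adjusted over the list alone, camera adjusted p = 1.23e-10 for lower, adjusted p = 0.471 with an estimated correlation), with col-92 (-2.72 ± 0.44) lower and col-158 (1.82 ± 0.34) and col-76 (0.90 ± 0.17) higher. In the intracellular pathogen response 9 were higher, 1 were lower and 14 did not pass of 24 tested (10 were higher and 1 were lower adjusted over the list alone, camera adjusted p = 0.00416 for higher, adjusted p = 0.471 with an estimated correlation). pals-6 (3.41 ± 0.35) and skr-4 (1.82 ± 0.21) were higher. pqm-1 differed by 2.26 ± 0.10 (adjusted p = 1.36e-07). Of 13324 genes 1900 passed, 1051 higher and 849 lower in rhd90, and 1102 passed without replicate 2 of the ok485 double mutant, 947 without replicate 1 and 1069 without replicate 3 of the rhd90 double mutant.

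**Figure D3:**
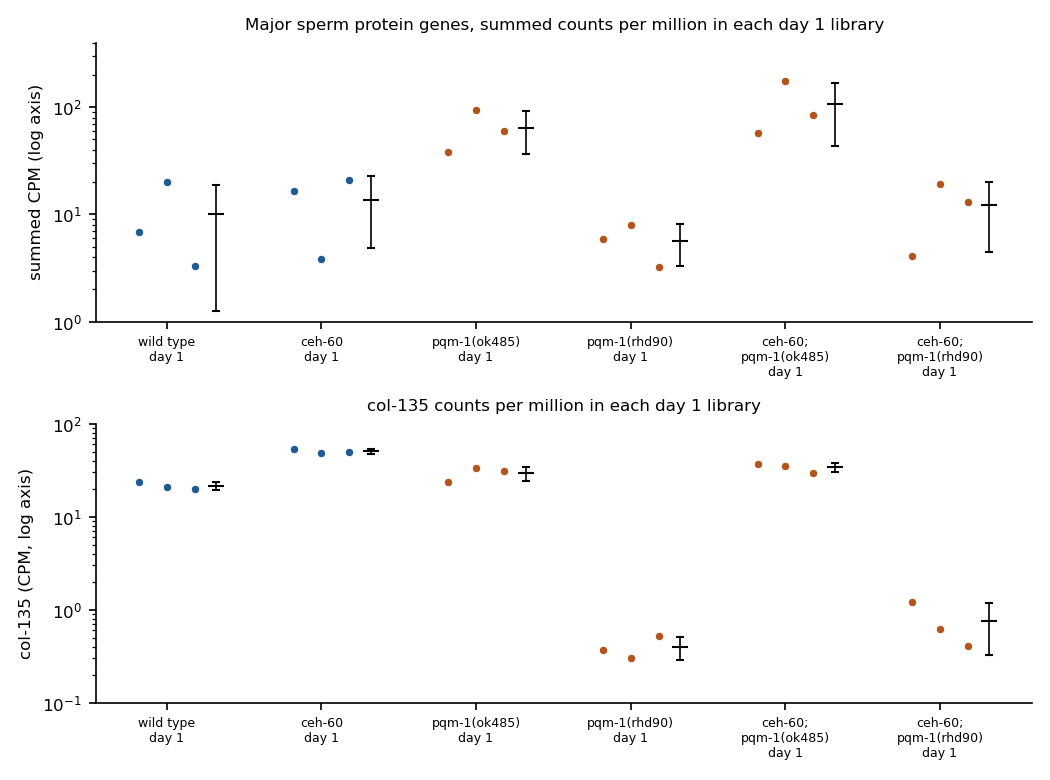
Summed CPM of the major sperm protein genes, not TMM-scaled (upper panel), and CPM of col-135 scaled by TMM within each table (lower panel), both on log axes, in each day 1 library (points; blue, first table; orange, second table), with the mean ± SD of 3 libraries per group as a black bar. Both ok485 groups have the highest sperm sums, 63.8 ± 27.5 and 106 ± 62.3 CPM against 5.71 ± 2.4 and 12.2 ± 7.71 in the rhd90 groups, and col-135 is at 0.395 ± 0.108 and 0.747 ± 0.423 CPM in the rhd90 groups against 29.3 ± 5.22 and 33.9 ± 3.75 in the ok485 groups.

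Comparisons of the pqm-1 mutants with wild type cross the tables, and genotype and table cannot be told apart there. pqm-1 transcripts were lower in pqm-1(ok485) than in wild type (-0.89 ± 0.09, adjusted p = 5.63e-06) and higher in pqm-1(rhd90) (0.43 ± 0.08, adjusted p = 0.00112). The arginine kinase gene argk-1 was higher in both, at 4.11 ± 0.43 and 4.00 ± 0.43. In ok485 col-81 (3.67 ± 0.80), col-39 (3.65 ± 0.65) and col-129 (3.51 ± 0.76) were also higher and WBGene00014955 (-2.16 ± 0.22) and WBGene00014954 (-2.1 ± 0.21) lower, and in rhd90 C08F11.7 (4.58 ± 0.19), F35F10.5 (2.89 ± 0.33) and cyp-35B2 (2.80 ± 0.36) were higher and col-135 (-5.66 ± 0.28), far-3 (-2.53 ± 0.32), Y69H2.3 (-2.50 ± 0.14) and F54F7.2 (-1.76 ± 0.25) lower. A total of 6480 genes differed for ok485 (3635 higher, 2845 lower, 4193 with only the compared groups fitted) and 3826 for rhd90 (2395 higher, 1431 lower), of 13589 tested.

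The summed counts of vit-1 to vit-6 gave the share of yolk protein transcripts per library. On day 1 the share was 6.43% ± 0.426 (SD, n = 3) of all counts in wild type and 0.412% ± 0.145 in ceh-60 mutants, a ratio of 15.6. On day 4 it was 5.17% ± 0.421 and 0.544% ± 0.0532, a ratio of 9.50. In the second table it was 9.11% ± 1.2 in pqm-1(ok485) against 0.159% ± 0.0689 in the ok485 double mutant, a ratio of 57.2, and 9.65% ± 0.218 in pqm-1(rhd90) against 0.218% ± 0.103 in the rhd90 double mutant, a ratio of 44.3. In each of these 4 comparisons the libraries did not overlap, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. That exact permutation test also gave p = 0.1 for wild type day 4 against day 1 and for the ok485 double mutant against the ceh-60 mutant, and p = 0.3 for ceh-60 day 4 against day 1 and for the rhd90 double mutant against the ceh-60 mutant. The pqm-1 mutants lay above wild type day 1 in every library (exact permutation p = 0.1 for each allele), again across the tables. These 10 tests cannot reach 0.05, with or without adjustment.

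**Figure D4:**
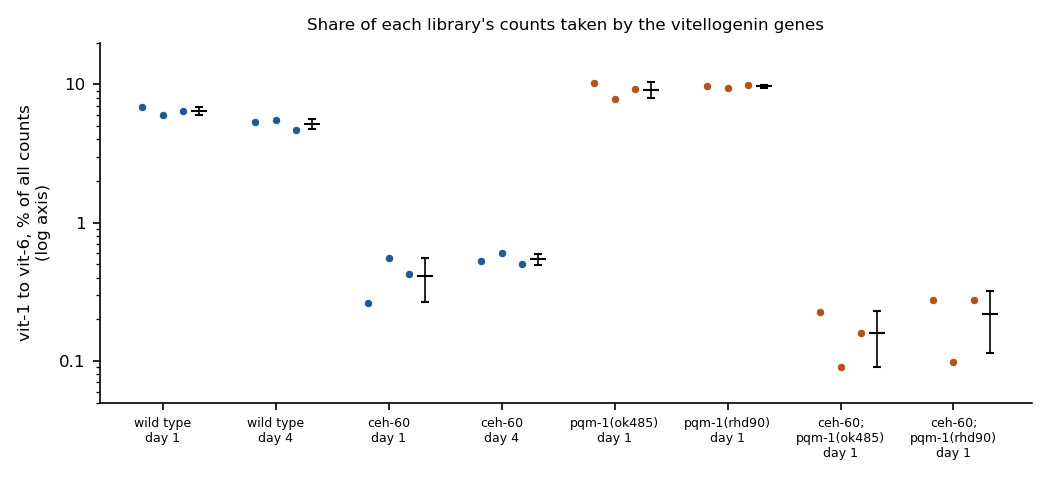
Counts of vit-1 to vit-6 as a percent of all counts assigned to genes, per library (points; blue, first table; orange, second table), with the mean ± SD of 3 libraries per group as a black bar. The 4 groups with ceh-60(ok1485) have means from 0.159% to 0.544%, and the 4 groups without it from 5.17% to 9.65%.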

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

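Of the tests reported in this part, the counts over other splits of the libraries, the test without pqm-1(ok485) replicate 1 and the comparison of the ceh-60 effect between the pqm-1 alleles were chosen only after the results were seen. Also, the requirement that the medians described below keep their sign with each library left out was added after the medians were known, which moved 1 explanation, a higher starting level, from excluded to open.

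Effects of ceh-60 loss that differed between the ages drew attention because the test of the difference itself passed. It did so for 531 genes, among them nhx-6 (-6.20 ± 1.16), tbb-6 (-3.84 ± 0.56), dod-3 (-3.70 ± 0.58) and clec-47 (-3.70 ± 0.35), with a lower effect on day 4, and acs-2 (2.86 ± 0.21) and F40F8.5 (2.14 ± 0.16), with a higher one. These calls and that of pqm-1 (-0.54 ± 0.09) held with each of the 12 libraries left out in turn. The call of clec-174 (5.15 ± 1.13) was lost for 2 of 12 libraries, wild type day 1 replicates 2 and 3. Adjusted p was 0.097 to 0.214 without them. vit-3 (2.01 ± 0.45) lost it for 7 of 12 libraries, wild type day 1 replicates 1 and 3, wild type day 4 replicates 1 and 3, ceh-60 day 1 replicate 3 and ceh-60 day 4 replicates 1 and 2. Adjusted p was 0.0513 to 0.0796 without them. vit-2 (0.98 ± 0.24) lost it for 9 of 12 libraries, wild type day 1 replicates 1, 2 and 3, wild type day 4 replicates 1, 2 and 3, ceh-60 day 1 replicate 3 and ceh-60 day 4 replicates 1 and 2. Adjusted p was 0.0665 to 0.119 without them. cyp-35A5 (2.17 ± 0.53) lost it for 10 of 12 libraries, wild type day 1 replicates 1, 2 and 3, wild type day 4 replicates 1, 2 and 3, ceh-60 day 1 replicate 1 and ceh-60 day 4 replicates 1, 2 and 3. Adjusted p was 0.0569 to 0.11 without them. Among 40 draws of regrouped libraries, 1 (the real one) gave as many genes, and the highest of the others gave 412. Such draws keep real ceh-60 effects, either as the effect of an arm whose labels stay true or as spread within mixed groups, so in this and the next 2 paragraphs they do not speak to chance. Whether chance can be excluded is therefore left open for the counts of these comparisons.

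The ceh-60 effect also differed between pqm-1(ok485) and the wild type background, for 602 genes. Calls held with each library left out for Y50D7A.10 (-5.09 ± 0.28), F55G11.4 (-2.69 ± 0.44), vit-2 (-2.0 ± 0.36), ZC317.7 (0.76 ± 0.17), Y46H3C.7 (0.66 ± 0.14) and pqm-1 (-1.67 ± 0.12). vit-6 (-2.57 ± 0.66) lost its call for 7 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicates 2 and 3, pqm-1(ok485) replicate 1 and ok485 double mutant replicates 2 and 3. Adjusted p was 0.052 to 0.0887 without them. vit-5 (-2.43 ± 0.60) did so for 6 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicate 2, pqm-1(ok485) replicate 1 and ok485 double mutant replicates 2 and 3. Adjusted p was 0.0504 to 0.0887 without them. vit-4 (-1.46 ± 0.37) lost its call for 6 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicates 2 and 3 and ok485 double mutant replicates 2 and 3. Adjusted p was 0.0562 to 0.108 without them, and 0.0832 with only the compared groups fitted. dod-21 (4.27 ± 1.05) lost the call for 8 of 12 libraries, wild type replicates 1 and 2, ceh-60 replicate 3, pqm-1(ok485) replicates 1, 2 and 3 and ok485 double mutant replicates 1 and 3. Adjusted p was 0.0517 to 0.0602 without them. asp-12 (2.13 ± 0.50) lost it for 6 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicate 1, pqm-1(ok485) replicates 2 and 3 and ok485 double mutant replicate 1. Adjusted p was 0.0507 to 0.0773 without them. Of 40 draws of regrouped libraries 4 gave as many genes, and the highest of the others gave 1661. A count several times the real one points to a structure of the samples: the high draws were among the 9 that kept the true labels of 1 background and with them its ceh-60 effect.

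For the rhd90 background against wild type, 37 genes differed. vit-2 (-3.39 ± 0.36), cls-3 (-1.98 ± 0.12), WBGene00014954 (1.85 ± 0.27), WBGene00014955 (1.79 ± 0.28), F36D3.1 (0.68 ± 0.09) and pqm-1 (-0.74 ± 0.11) kept their calls with each library left out. C15A11.7 (-1.61 ± 0.32) lost its call for 9 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicate 3, pqm-1(rhd90) replicates 1, 2 and 3 and rhd90 double mutant replicates 1, 2 and 3. Adjusted p was 0.06 to 0.143 without them, and 0.116 with only the compared groups fitted. nspg-11 (-1.3 ± 0.24) lost it for 8 of 12 libraries, wild type replicates 2 and 3, ceh-60 replicates 1 and 3, pqm-1(rhd90) replicates 1 and 3 and rhd90 double mutant replicates 2 and 3. Adjusted p was 0.0521 to 0.0993 without them. usp-50 (0.62 ± 0.12) lost it for 7 of 12 libraries, ceh-60 replicates 1 and 3, pqm-1(rhd90) replicates 1 and 3 and rhd90 double mutant replicates 1, 2 and 3. Adjusted p was 0.0628 to 0.0993 without them. Of 40 draws 6 gave as many genes, at most 1891, again with 1 background's true labels kept. Between the pqm-1 alleles 46 genes differed. Y50D7A.10 (5.14 ± 0.34), vit-5 (3.58 ± 0.48), hid-1 (2.06 ± 0.14), cls-3 (-2.15 ± 0.14) and pqm-1 (0.97 ± 0.14) held throughout. WBGene00020981 (1.98 ± 0.29) lost its call for 4 of 12 libraries, pqm-1(rhd90) replicates 1 and 2 and ok485 double mutant replicates 2 and 3. Adjusted p was 0.0505 to 0.0612 without them. W02D7.6 (-0.54 ± 0.09) lost it for 8 of 12 libraries, pqm-1(ok485) replicate 2, pqm-1(rhd90) replicates 2 and 3, ok485 double mutant replicates 1, 2 and 3 and rhd90 double mutant replicates 1 and 3. Adjusted p was 0.0594 to 0.107 without them. fbxa-192 (-1.05 ± 0.17) lost it for 9 of 12 libraries, pqm-1(ok485) replicates 2 and 3, pqm-1(rhd90) replicates 2 and 3, ok485 double mutant replicates 1, 2 and 3 and rhd90 double mutant replicates 1 and 3. Adjusted p was 0.0542 to 0.1 without them. Here 2 of 40 draws gave as many, the highest other 100.

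The size of the ceh-60 effect was compared over 2074 genes called higher in ceh-60 than in wild type on day 4, in libraries outside this test. Its median on day 1 was 0.605 in wild type, 0.131 in ok485 and 0.361 in rhd90, on the log2 scale. These genes were chosen as raised in the wild type background, which favours a smaller effect in any other background. No set chosen in a pqm-1 background was tried. The median difference was -0.437 (bootstrap interval -0.454 to -0.423, -0.549 to -0.364 with each library left out) in ok485 and -0.222 in rhd90. The narrower bootstrap interval does not measure the spread between libraries. A shift shared by a table cancels here and is not tested. A ceh-60 effect that differs between tables does not cancel and stays open. That pqm-1(ok485) replicate 1, which stands apart, was alone the source of the 602 genes is argued against, since 561 passed without it. With each library left out the count ran from 220 (ceh-60 replicate 1) to 1044 (wild type replicate 1), so it depends on other libraries. Whether these genes start higher in pqm-1(ok485) stays open: rhd90 minus ok485 in ceh-60(+) animals had a median of -0.0207 (-0.0548 to 0.0378 with each library left out). In ceh-60 mutants the same median was 0.22 (0.171 to 0.281), close to the gap between the 2 backgrounds already given. A lower final level in the ok485 double mutant may describe where that gap lies, but not the whole difference from wild type. The part that rhd90 shares stays open, since levels against wild type cross the tables and the genes were chosen in the wild type background. An untested biological difference in what the alleles do to pqm-1 stays open as well.

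For 3 libraries against 3, the 10 splits are too few for a share under 0.05. By edgeR, the only tool used, only the real one gave as many genes in each. Other splits mix the groups, so real effects become spread and 0 calls do not speak to chance. Real counts are given with, in parentheses, the other splits' highest count and highest number at an unadjusted p under 0.05. They were 3354 (0, 2301) for ceh-60 on day 1, 3201 (0, 1585) on day 4, 7193 (0, 443) for age in wild type, 6909 (0, 1708) for age in ceh-60, 1195 (0, 1119) for the ok485 background, 1581 (0, 1129) for the rhd90 background, 1900 (0, 1475) for the alleles in ceh-60, 6480 (0, 1655) for ok485 and 3826 (0, 1058) for rhd90 against wild type. For rhd90 against ok485 on day 1 they were 984 (931, 3764). There the split with 931 genes set pqm-1(ok485) replicate 1 with pqm-1(rhd90) replicates 1 and 3 and so kept a same-numbered pair together, and the 3 other splits that part all 3 pairs, as the real one does, gave at most 0.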

How the results depend on the processing

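The comparison rhd90 minus ok485 background was added after the counts of both backgrounds had been seen, with the same alternatives as the others. Under all alternatives, 18157 values of named genes were recomputed: 16386 kept their side of the threshold, 1701 no longer passed and 70 newly passed. Direction was checked only for genes that passed in the main fit, of which 0 reversed. Of 314 counts, 215 stayed within 1.5 times the main value and 99 moved. Asking for at least 2-fold left 978 (ceh-60 on day 1), 897 (on day 4), 236 (their difference), 1778 (age in wild type), 1790 (age in ceh-60), 420 (the ok485 background), 580 (the rhd90 background), 214 (ok485 minus wild type), 15 (rhd90 minus wild type), 570 (the alleles), 932 (the alleles in ceh-60), 1450 (ok485 against wild type), 520 (rhd90 against wild type) and 29 (rhd90 minus ok485 background) genes, since this asks for more. Shared at 2-fold were 367 higher and 29 lower for days 1 and 4, 192 and 56 for day 1 with ok485, 422 and 40 with rhd90 and 196 and 54 for both backgrounds. With 1 library left out, counts ranged over 1899 to 3482 (ceh-60 on day 1), 2450 to 3148 (on day 4), 306 to 567 (their difference), 6408 to 6653 (age in wild type), 5971 to 6565 (age in ceh-60), 738 to 1106 (the ok485 background), 1072 to 1479 (the rhd90 background), 220 to 1044 (ok485 minus wild type), 14 to 69 (rhd90 minus wild type), 187 to 2186 (the alleles), 947 to 2123 (the alleles in ceh-60), 4544 to 5972 (ok485 against wild type), 2555 to 3709 (rhd90 against wild type) and 14 to 100 (rhd90 minus ok485 background), where the remaining libraries of a group were fewer. Without a filter on low counts 905 genes differed between the ages, 151 for rhd90 minus wild type and 96 for rhd90 minus ok485. DESeq2 gave 920 for ok485 minus wild type and 101 for rhd90 minus wild type. For rhd90 minus ok485 it gave 106 higher and 13 lower, 1.2e+02 in all after rounding. Fitting only the compared groups gave 616 for the alleles, 388 for ok485 minus wild type and 4193 for ok485 against wild type. The cause was not tested for these last 3 settings.

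With the replicate number as a block, 2160 genes passed for the ok485 background and 2069 for the alleles, where the numbers pair the libraries, and no gene named in the report lost its call. In the others not every pair of same-numbered libraries correlated above 0.1, although the interactions include groups that the numbers pair, and the block gave 3274 for the alleles in ceh-60, 1791 for ok485 minus wild type, 332 for rhd90 minus wild type and 241 for rhd90 minus ok485, with other counts within 1.5 times. In those comparisons of 2 groups, in the order ceh-60 on day 1, on day 4, age in wild type, age in ceh-60, rhd90 background, alleles in ceh-60, ok485 and rhd90 against wild type, 2, 4, 4, 5, 4, 4, 6 and 3 of 6 libraries correlated best with their own number.

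Camera called 25 (ceh-60 on day 1), 19 (on day 4), 14 (their difference), 12 (age in wild type), 12 (age in ceh-60), 24 (the ok485 background), 19 (the rhd90 background), 23 (ok485 minus wild type), 17 (rhd90 minus wild type), 11 (the alleles), 15 (the alleles in ceh-60), 20 (ok485 against wild type), 20 (rhd90 against wild type) and 12 (rhd90 minus ok485 background) of the 35 lists with the preset correlation. It called 0 in every comparison with an estimated one. In the same order, 11, 9, 1, 2, 4, 6, 7, 3, 3, 3, 2, 2, 4 and 2 had an unadjusted p under 0.05. Fry, which asks whether a list moves at all, called 26, 19, 0, 25, 24, 15, 17, 18, 0, 8, 10, 28, 20 and 3. The estimated correlation was above the preset one in nearly all tests, which lowers the weight camera gives a list. Leaving the 50 most abundant other genes out of the denominator moved the difference in vitellogenin share between ceh-60 mutants and their controls, in percentage points, from -6.019 to -6.925 (day 1), -4.622 to -5.148 (day 4), -8.947 to -10.21 (ok485) and -9.429 to -10.77 (rhd90), because the total shrank. Depth limits values near the floor, such as those of ceh-60 and of vit and msp genes in groups where they fall to a few CPM.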

Other observations

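In this part, the count of neighbouring genes was chosen as a test after the genes were seen. The genes named without a rule were chosen after their values were seen. Before the test of males other male genes (pkd-2, lov-1 and klp-6) had been seen to lie near the floor. Major sperm protein transcripts were low in the first table, with summed levels, not TMM-scaled, of 10.1 ± 8.82 CPM (mean ± SD, n = 3) in wild type day 1, 7.20 ± 6.92 in wild type day 4. They were 13.7 ± 8.84 in ceh-60 day 1 and 0.366 ± 0.285 in ceh-60 day 4. In the second table they were 63.8 ± 27.5 in pqm-1(ok485), 106 ± 62.3 in the ok485 double mutant, 5.71 ± 2.4 in pqm-1(rhd90) and 12.2 ± 7.71 in the rhd90 double mutant. The wild type day 4 libraries spread widely, from 1.52 to 14.9 CPM. argk-1, which encodes an arginine kinase, and cth-1, a cystathionine gamma-lyase gene, were higher in every library of the second table than in every library of the first. After TMM scaling over the 18 day 1 libraries, cls-3 stood at 90.7 ± 5.07 CPM in pqm-1(rhd90) against 22.8 ± 0.429 in the rhd90 double mutant, 27.1 ± 1.33 in ceh-60 and 27.5 ± 2.24 in wild type day 1. Among the groups of the second table, with TMM scaling within it, hid-1 and Y50D7A.10 were lowest in the ok485 double mutant, at 5.94 ± 0.566 and 0.229 ± 0.184 CPM.

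Replicate 1 of ceh-60 day 1 had 0.644% of its counts on ribosomal RNA genes, against 0.034% to 0.427% in the others. The 10 most abundant genes took 4.36% to 13.1% of the counts of a library, with the lowest shares in libraries that carry ceh-60(ok1485). The mitochondrial genome took 0.546% to 1.06% of counts.

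Sperm gene transcripts were higher in both ok485 groups than in both rhd90 groups. If the ok485 animals were younger or less synchronous, the allele difference outside sperm and collagen genes might follow the change with age. The smaller of the 2 correlations across genes, which are not independent replicates, was 0.0607 and the other 0.168, over 12579 genes, which does not decide it. If males were present, transcripts of 7 male neuron genes should be higher. Their summed level, not TMM-scaled, was 0.378 ± 0.29 CPM in the 6 ok485 libraries and 0.264 ± 0.142 in the 6 rhd90 libraries, a ratio of 1.43 (two-sided exact permutation p = 0.424), too near the floor to tell. A younger culture, males and a biological effect of the allele on sperm cannot be told apart here.

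Neighbouring genes on chromosome IV differed together in both rhd90 groups. Of the 7 genes whose 6 rhd90 libraries all lay at least 1 log2 unit away from the other 12 day 1 libraries on the same side, 2 pairs lie within 10 kb (levels TMM-scaled over the 18 day 1 libraries). The first pair is col-135 (chromosome IV, 15129666 to 15131797, 0.57 CPM against 32.9) with clec-190 (chromosome IV, 15124931 to 15126122, 0.157 CPM against 1.94), both lower. The other is C08F11.7 (chromosome IV, 13637288 to 13638525, 11.2 CPM against 0.478) with WBGene00014672 (chromosome IV, 13636560 to 13636975, 2.89 CPM against 0.295), both higher. The pairs were noticed before they were counted and no sequence data were at hand, so a DNA difference at these loci carried by the rhd90 strains, expression shared by neighbouring genes and an effect of pqm-1, which lies on chromosome II, on these genes cannot be told apart.

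It was asked whether genes raised without ceh-60 are those that rise with age. The ceh-60 effects in the pqm-1 backgrounds, which share no library with wild type ageing, correlated with it across genes at r = 0.0496 (ok485) and 0.163 (rhd90). In ok485 204 genes were higher in both (175 for independent lists), 241 lower in both (151) and 315 opposite, and in rhd90 461 (362), 148 (74.4) and 398. These values might hold a small shared part, but they do not decide the question.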
